A study of Homo sapiens with 12 samples.

How the data were processed

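Gene expression was measured on 12 Affymetrix arrays in human endothelial cells from the cord blood of 4 donors. Each donor gave 1 array in each of 3 groups of culture, named here networks, layers and monoculture. Per the labels, the networks and layers arrays came from lamellar co-cultures with smooth muscle cells and the monoculture arrays from endothelial cells grown alone. Per the labels' protocols, total RNA was taken from the co-cultures or the monocultures with a column kit and treated with DNase. A step that parted endothelial from smooth muscle cells before lysis is not given in the sources used here, so the co-culture values are read as those of the whole culture extract. The group and the donor number of each array were taken from its labels.

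The deposited table holds 1 log2 value per probe set and array. Per the submitters' processing notes, the authors made it with RMA, whose version is not given in the sources used here. RMA corrects the background, brings all arrays to the same distribution by quantile normalization and sums the probes of a probe set into a single log2 value. The log2 scale was read from the values, which ran from 2.68 to 15.03 with array medians from 6.43 to 6.52. Quantile normalization removes a change shared by most genes, and intensities near the background understate fold changes, so the fold changes of dim genes are compressed. Arrays have no count of reads, and the number of arrays limits the precision. The scanner files were not used here.

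Probe sets were named from the platform annotation. Of 54675 probe sets, 41097 named 1 gene, 1801 named several and 11777 were unnamed here. The 62 control probe sets, those without a single gene, and 73 probe sets of XIST, TSIX and Y-linked genes were left out before any test, which left 41018 probe sets of 19732 genes. A probe set was tested where at least 4 arrays lay above the median of the whole table (6.48). Each gene was represented by its probe set with the highest mean over the 12 arrays, which gave 13346 genes. Of 84 named genes that passed the test in networks against monoculture, 45 had other probe sets. All of these passed in the same direction for 35 genes and none passed for NOTCH3, HSP90B1, MFNG, VWF, GJA4 and LRATD2. Of 67 in layers against monoculture, 38 had other probe sets, all of which passed for 28 genes and none for SEMA3C, NOTCH3, ITGA11, VEGFA, PLXNA1 and TAL1. No other probe set of a named gene passed in the opposite direction. No genome coordinates were used.

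The 3 groups were fitted in a single linear model per gene with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, over all 12 arrays without a term for the donor. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05. The comparisons were networks against monoculture, layers against monoculture and networks against layers. Figures were drawn with matplotlib 3.10.9.

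The test, the samples in it, 26 gene lists and the rule for named genes were fixed before the data were examined. The lists cover smooth muscle contractile genes, mural and fibroblast markers, interstitial matrix, basement membrane, endothelial identity, tip cell and sprouting, Notch signalling, arterial endothelial, venous and lymphatic endothelial, flow-responsive quiescence, mitosis, DNA replication, matrix proteases and inhibitors, TGF-beta and BMP response, NF-kB inflammatory, interferon response, hypoxia and glycolysis, cholesterol synthesis, YAP and SRF targets, integrins, cell junctions, immediate early genes, unfolded protein and amino acid response, vascular growth factors and receptors, axon guidance, and leukocyte and erythroid markers. Lists were tested with camera at a preset correlation of 0.01, with adjustment over the 26 lists, and again with a correlation estimated per list. The named genes were the 10 largest rises and 10 largest falls among genes that passed and moved the same way in all 4 donors, up to 2 rising and 2 falling genes that passed per list, and always PECAM1, CDH5, VWF, KDR, ACTA2, TAGLN, CNN1, MYH11, COL1A1 and MKI67.

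The labels give the same 4 donors in every group, so the donor numbers pair the arrays. Across genes, the deviations of same-donor arrays from their group means correlated at 0.67 to 0.86 between networks and layers, at -0.11 to 0.24 between networks and monoculture and at -0.10 to 0.40 between layers and monoculture. The paired analyses had the donor as a fixed block, as a random block (statmod 1.5.0), and, chosen after seeing the data, as a fixed block over the 8 arrays of the groups compared. The other alternatives were no filter or a filter at the 75th percentile, the mean of a gene's probe sets, every probe set, median centring, repeated quantile normalization, a fit over 8 arrays, array weights, a trended robust eBayes, a fold change of at least 2, and leaving out each array. Fits without replicate 1, and without its 2 co-culture arrays, were also chosen after seeing the data. The list tests with the donor as a random block were not run.

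The code was tested on simulated data with 13346 genes and the spread of these arrays. At a log2 change of 0.5, 1 and 2, the fit recovered 55.2%, 86.6% and 98.5% of changed genes for networks against monoculture, 47.8%, 89.6% and 92.4% for layers against monoculture, and 53.7%, 85.1% and 95.5% for networks against layers. A simulated list shift of 0.5 was called in each of the 3 comparisons, and 0 of 25 other lists were. The simulated genes varied independently, whereas the estimated correlation of the real lists reached 0.72 for mitosis. This simulation therefore cannot show how often lists of correlated genes are called falsely.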

Results

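Gene expression was profiled in 3 kinds of culture of endothelial cells from the cord blood of 4 donors, with 4 arrays each. The co-culture values are read as those of the whole culture extract. In the networks group the endothelial cells lay in networks within co-cultures with smooth muscle cells. In the layers group they lay, per the labels, in confluent layers within such co-cultures, and in the monoculture group they grew alone. The stated purpose was to find the molecular mechanisms behind endothelial network formation. Arrays of the same group correlated at 0.980 to 0.996 across probe sets, and 0 pairs were identical. The first principal component held 65.3% of the variance and ran from -46.1 to -42.9 in monoculture, from -16.6 to 39.2 in layers and from 4.09 to 42.9 in networks. The array medians and the 3' to 5' differences of the GAPDH and ACTB controls gave p from 0.200 to 1 between groups in 9 exact 2-sided permutation tests. With 4 arrays per group the smallest p possible was 0.0286, so no single measure could pass after adjustment over the 9 tests. The titles of the networks and the layers arrays begin with different prefixes whose meaning is not given. If these name different smooth muscle cell preparations, that difference cannot be separated from networks against layers.

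Networks held far more mRNA of interstitial matrix genes and mesenchymal markers than monocultures, and less mRNA of mitosis and DNA replication. COL6A3, a chain of type VI collagen, rose 308-fold, from a log2 intensity of 5.47 ± 0.53 to 13.74 ± 1.06 (SD, n = 4 each). VCAN, the proteoglycan versican, rose 274-fold and COL1A1, a chain of type I collagen, rose 263-fold. All 30 mitosis genes measured fell, by a median of 1.98-fold. Among genes bright in monoculture, ALDH1A1, a retinaldehyde dehydrogenase, fell 9.29-fold and BMP4, a secreted bone morphogenetic protein, fell 8.30-fold.

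In limma, 3088 of 13346 genes changed between networks and monoculture, 1529 up and 1559 down, of which 777 changed at least 2-fold (558 up, 219 down). The values of the groups did not overlap for 26.0% of genes, against 2.86% by chance. The 10 largest rises, which also included HSD11B1, DCN, COL3A1, PDGFRA, IL13RA2, THBS2 and MFAP5, lay between 6.36 and 8.27 on the log2 scale (adjusted p from 1.31e-05 to 0.00325). The 10 largest falls, ADAMTS18, ALDH1A1, BMP4, LRATD2, TPD52, MYRIP, GDF7, GPC5, MATN2 and ART4, lay between -3.39 and -2.49 (adjusted p from 4.94e-05 to 0.0115). Each of these 20 genes moved the same way in all 4 donors. All of these rising genes but COL3A1 lay below the table median of 6.48 in monoculture, where intensities near the background understate fold changes. The folds are also estimates with error (COL6A3 8.27 ± 0.89 on the log2 scale, IL13RA2 6.44 ± 1.19, SE), and their order is uncertain.

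The matrix and mesenchymal lists were the most raised in networks. Of 25 interstitial matrix genes measured, 16 rose, 2 fell and 7 did not pass, with a median 6.60-fold higher (camera adjusted p = 3.87e-10). With an estimated correlation this list had an adjusted p = 0.209, and adjusted over the list alone 20 rose and 3 fell. Of 20 mural and fibroblast markers, 12 rose, among them the receptor PDGFRA (96.3-fold) and the microfibril protein MFAP5 (81.9-fold). This list had an adjusted p = 2.08e-08 and an adjusted p = 0.198 with an estimated correlation, and adjusted over the list alone 16 rose and 1 fell. Of 18 smooth muscle contractile genes, 8 rose and 1 fell, with 10 up and 1 down adjusted over the list alone. The list had an adjusted p = 0.000481, and an adjusted p = 0.198 with an estimated correlation. ACTA2, smooth muscle actin, rose 36.7-fold (56.4-fold without networks replicate 1) and TAGLN, transgelin, 12.7-fold, while CSRP1 fell by 0.54 on the log2 scale. MYH11, the smooth muscle myosin heavy chain, differed by -0.15 ± 0.08 (SE, adjusted p = 0.217). CNN1, calponin, differed by 1.06 ± 0.38 (adjusted p = 0.0659) and passed with the donor as a block (adjusted p = 0.0446). Both genes were dim. MYH11 averaged 7.13 in monoculture and 6.98 in networks, little above the table median of 6.48. CNN1 averaged 5.21 and 6.28, below it. At such levels the lack of a call says little about whether a gene changed. Of the genes measured, 11 of 20 mural markers, 18 of 25 matrix genes and 16 of 18 contractile genes lay above the table median in monoculture as well, and other lists held 3, 1 and 0 of them.

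**Figure D1:**
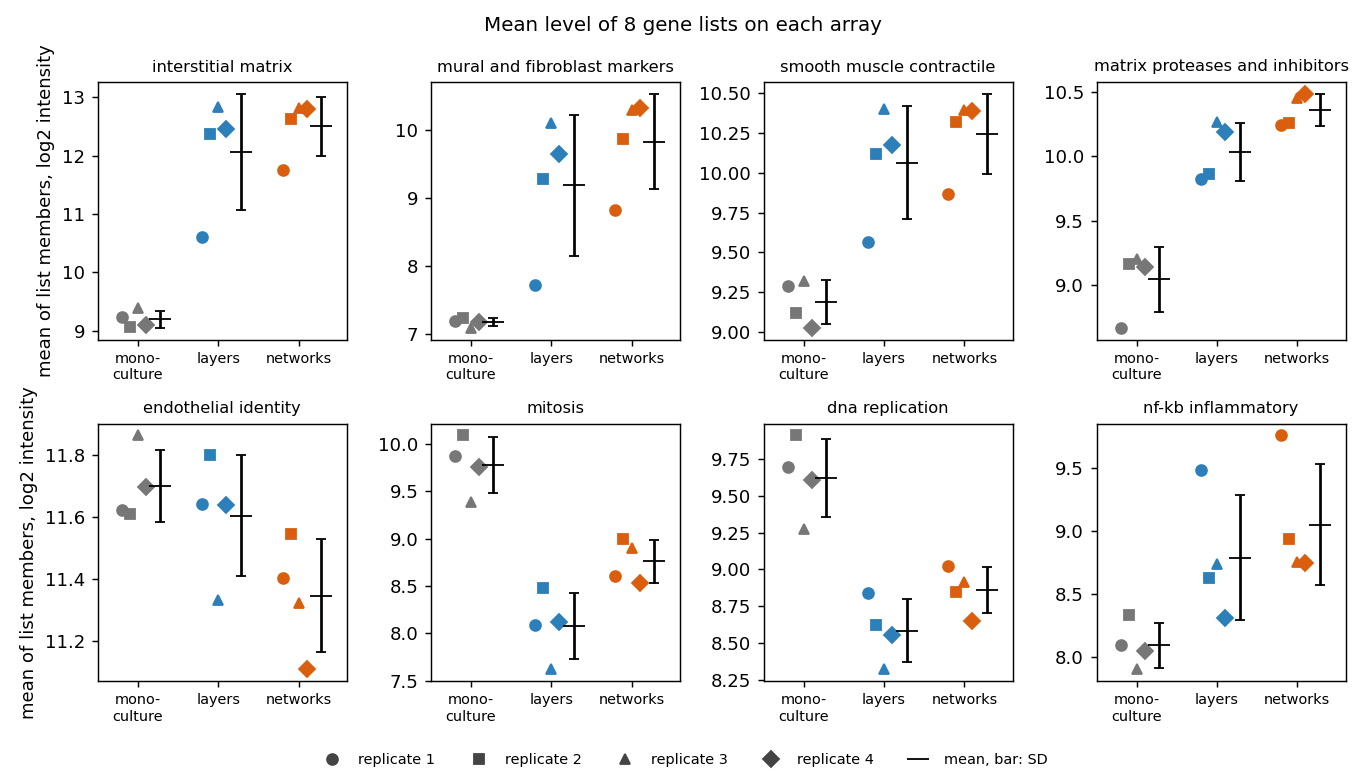
Mean log2 intensity of the measured members of 8 gene lists on each of the 12 arrays, with 1 panel per list, points shaped by donor, and the group mean with a bar of 1 SD (n = 4). The mural and fibroblast list lay from 7.08 to 7.22 in monoculture and at 7.71 and 8.83 in replicate 1 of layers and networks, against 9.29 to 10.33 in the other co-culture arrays.

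The mesenchymal markers varied between co-culture arrays. In networks the mural and fibroblast list averaged 8.83 in replicate 1 and 9.87 to 10.33 in the other replicates, and the interstitial matrix list averaged 11.75 and 12.63 to 12.82. The smooth muscle contractile list of replicate 1 averaged 9.87, against 10.32 to 10.39. Without the 2 co-culture arrays of replicate 1, a fit chosen after seeing the data, 4394 genes changed between networks and monoculture.

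Matrix turnover and adhesion genes were also higher in networks than in monoculture. In networks replicate 1, against its other replicates, the median difference was -1.38 for the mural and fibroblast list and -0.33 for basement membrane. It was -0.12 for matrix proteases and inhibitors and 0.30 for integrins. Of 25 matrix proteases and inhibitors, 14 rose (14 up and 1 down adjusted over the list alone), with a median 1.85-fold higher. This list had an adjusted p = 2.59e-07, and it passed with an estimated correlation too (adjusted p = 0.0259). The inhibitors TIMP3 and SERPINE2 rose 28.1-fold and 11.97-fold. Of 17 basement membrane genes 6 rose (6 up and 1 down adjusted over the list alone), FBLN2 by 15.0-fold (adjusted p = 0.00734 for the list and 0.438 with an estimated correlation). Of 15 integrins 6 rose (7 adjusted over the list alone), among them ITGA11 (5.92-fold) and ITGA4 (4.04-fold). Their list had an adjusted p = 0.0119, an adjusted p = 0.198 with an estimated correlation and an adjusted p = 0.0876 without replicate 1.

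Endothelial identity genes were mostly lower in networks than in monoculture, 30 of 35 in mean, though fewer passed. Of 35 endothelial identity genes 15 fell, 2 rose and 18 did not pass, with a median log2 change of -0.34 (adjusted p = 0.000387). The list had an adjusted p = 0.394 with an estimated correlation, and adjusted over the list alone 16 fell and 2 rose. Other lists held 11 of its genes. MMRN1 fell 2.69-fold, the transcription factor TAL1 2.25-fold and VWF, von Willebrand factor, 1.71-fold, though the other VWF probe set did not pass. PLVAP, a protein of fenestral diaphragms, rose 3.73-fold and the transcription factor ETS1 2.23-fold. The junction genes PECAM1 and CDH5 differed by -0.10 ± 0.14 (SE, adjusted p = 0.666) and -0.52 ± 0.17 (adjusted p = 0.0483), and the VEGF receptor KDR by 0.37 ± 0.20 (adjusted p = 0.219). The CDH5 call ended with the donor as a block (adjusted p = 0.0578) and without any of 8 arrays (adjusted p from 0.0532 to 0.135), namely networks replicates 2, 3 and 4, layers replicates 2 and 4, and monoculture replicates 1, 3 and 4.

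Of 19 tip cell and sprouting genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), including the receptors APLNR (19.1-fold) and CXCR4 (5.71-fold). That list did not pass (adjusted p = 0.0571), and had an adjusted p = 0.231 with an estimated correlation. With the donor as a block it passed (adjusted p = 0.0257), but not with an estimated correlation too (adjusted p = 0.269). Other lists held 12 of its genes. Of 14 flow-responsive genes 5 rose and 1 fell, led by CYP1B1 (37.5-fold), ADAMTS1 (11.7-fold) and, falling, CYP1A1 (4.81-fold). With 8 up and 1 down adjusted over the list alone, this list had an adjusted p = 0.000753 and an adjusted p = 0.0959 with an estimated correlation. Notch signalling (4 of 21 up, 1 down, adjusted p = 0.185), arterial (4 of 14 up, 2 down, adjusted p = 0.121) and venous and lymphatic genes (2 of 10 up, 2 down, adjusted p = 0.529) did not pass as lists. Adjusted over the list alone, 4, 5 and 4 of them rose and 1, 2 and 2 fell. HEY1, a Notch target, rose 4.16-fold, and LYVE1, a lymphatic hyaluronan receptor, rose 8.57-fold. The venous and lymphatic list had a median of -0.06 and a mean of 0.58.

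Cell cycle genes fell together in networks. All 30 mitosis genes fell over all genes tested and adjusted over the list alone (adjusted p = 8.64e-14, adjusted p = 0.209 with an estimated correlation), among them CDC20 (2.75-fold) and MKI67 (1.74-fold). Of 27 DNA replication genes 24 fell (26 adjusted over the list alone), by a median of 1.78-fold, with RRM2, a subunit of ribonucleotide reductase, down 2.88-fold. That list had an adjusted p = 1.25e-10, and an adjusted p = 0.209 with an estimated correlation.

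Of 21 NF-kB inflammatory genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with the cytokines CXCL6 and IL6 up 53.2-fold and 13.3-fold and the adhesion molecule VCAM1 down 3.50-fold (list adjusted p = 0.000481, adjusted p = 0.231 with an estimated correlation). Networks replicate 1 stood apart here, with a list mean of 9.76 against 8.75 to 8.94, and without networks replicate 1 CXCL6 rose 30.0-fold. Of 19 immediate early genes 10 rose and 1 fell (15 and 2 adjusted over the list alone), FOS by 3.94-fold (adjusted p = 7.06e-06, adjusted p = 0.198 with an estimated correlation). Of 25 hypoxia and glycolysis genes 11 rose (16 adjusted over the list alone), including VEGFA (4.498-fold) and the prolyl hydroxylase subunit P4HA2 (3.58-fold), with an adjusted p = 2.35e-08 for the list and 0.198 with an estimated correlation. Of 19 unfolded protein and amino acid response genes 5 rose and 1 fell (9 and 1 adjusted over the list alone), with asparagine synthetase ASNS up 5.85-fold (adjusted p = 0.00105, adjusted p = 0.231 with an estimated correlation). In replicate 1, against the other replicates, the immediate early, hypoxia and unfolded protein lists were lower, as was the mural and fibroblast list. The median differences of these 3 lists were -0.23, -0.40 and -0.33 in networks and -0.42, -0.49 and -0.41 in layers. Of 28 vascular growth factors and receptors 9 rose and 3 fell (11 and 5 adjusted over the list alone), with IGFBP5 up 52.2-fold and PDGFD down 1.70-fold (adjusted p = 0.00605, adjusted p = 0.198 with an estimated correlation).

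The remaining lists did not pass in networks against monoculture. TGF-beta and BMP response genes went both ways, with 6 of 25 up and 3 down (6 and 4 adjusted over the list alone), a median of -0.21, a mean of 0.16 and an adjusted p = 0.691. TGFBI rose 40.9-fold and the inhibitor of differentiation ID2 7.01-fold, and BMP6 fell 2.71-fold. The counts up and down were 2 and 0 of 23 for interferon response (adjusted p = 0.185), 0 and 3 of 16 for cholesterol synthesis (adjusted p = 0.148), 1 and 4 of 16 for YAP and SRF targets (adjusted p = 0.260), 1 and 3 of 18 for cell junctions (adjusted p = 0.185), and 6 and 5 of 27 for axon guidance (adjusted p = 0.529). Adjusted over the list alone they were 2 and 0, 0 and 2, 1 and 5, 1 and 3, and 6 and 5. Of 5 measured leukocyte and erythroid markers 0 changed, over all genes or adjusted over the list alone (adjusted p = 0.998).

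Layers, like networks, held more mRNA of matrix and mesenchymal genes and less of mitosis genes than monocultures. COL6A3 rose 190-fold, to 13.04 ± 2.13 (SD, n = 4), COL1A1 rose 169-fold and VCAN 156-fold. Layers replicate 1 stood apart in these genes, and without layers replicate 1 the rises were 396-fold, 302-fold and 253-fold. All 30 mitosis genes fell, by a median of 3.32-fold, with CDC20 down 4.69-fold and MKI67 down 2.50-fold. Of 27 DNA replication genes 25 fell, by a median of 2.09-fold, with RRM2 down 5.43-fold.

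In limma, 1670 genes changed between layers and monoculture, 812 up and 858 down, of which 516 changed at least 2-fold (311 up, 205 down). The values of the groups did not overlap for 18.1% of genes, against 2.86% by chance. With the donor as a block, 2698 genes changed over all 12 arrays and 1148 over the 8 arrays compared. Without the block, 1003 changed without layers replicate 3 and 1035 without layers replicate 4. Without the 2 co-culture arrays of replicate 1, which had the lowest mural and fibroblast means, 3267 changed. The 10 largest rises were COL6A3, COL1A1, VCAN, COL3A1, HSD11B1, DCN, MFAP5, THBS2, PAPPA and PDGFRA, between 5.31 and 7.57 on the log2 scale, all but COL3A1 again from below the table median in monoculture. The 10 largest falls were TPD52, GDF7, RRM2, ART4, DEPDC1, PBK, CDC20, GUCY1A1, ADAMTS18 and DLGAP5, between -2.61 and -2.19.

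In layers, 15 of 25 interstitial matrix genes rose (16 up and 1 down adjusted over the list alone), with a median 5.05-fold higher (adjusted p = 1.02e-10, adjusted p = 0.141 with an estimated correlation). Of 20 mural and fibroblast markers 9 rose (10 adjusted over the list alone), with an adjusted p = 3.54e-07 and, with an estimated correlation, an adjusted p = 0.152. Of 18 contractile genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with an adjusted p = 0.000816 and an adjusted p = 0.115 with an estimated correlation. ACTA2 rose 27.5-fold (48.9-fold without layers replicate 1) and TAGLN 9.92-fold, whereas CNN1 (0.98 ± 0.38 SE, adjusted p = 0.123) and MYH11 (-0.11 ± 0.08, adjusted p = 0.459) did not pass. CNN1 and MYH11 were dim in layers too, at 6.19 and 7.03. The mural and fibroblast list averaged 7.71 in replicate 1 of layers and 9.29 to 10.11 in the others. Of 25 matrix proteases and inhibitors 12 rose (13 adjusted over the list alone), with an adjusted p = 6.63e-07, and the list passed with an estimated correlation (adjusted p = 0.0320). Basement membrane genes (4 of 17 up, 6 adjusted over the list alone) had an adjusted p = 0.000596, and an adjusted p = 0.266 with an estimated correlation. Integrins (4 of 15 up, 6 adjusted over the list alone) had an adjusted p = 0.0329 and lost the call with an estimated correlation (adjusted p = 0.141), with array weights (adjusted p = 0.0553), with the donor as a block over 8 arrays (adjusted p = 0.0507) and without layers replicate 1 (adjusted p = 0.0821).

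The endothelial identity list did not pass in layers, with 5 of 35 genes down and 2 up (6 and 2 adjusted over the list alone), a median of -0.15 and an adjusted p = 0.103. PECAM1 (0.03 ± 0.14 SE, adjusted p = 0.924), CDH5 (-0.34 ± 0.17, adjusted p = 0.236), VWF (-0.18 ± 0.18, adjusted p = 0.560) and KDR (0.56 ± 0.20, adjusted p = 0.0963) did not pass, and PLVAP and ETS1 rose 3.92-fold and 2.53-fold. Tip cell and sprouting genes (6 of 19 up, 9 adjusted over the list alone) had an adjusted p = 0.000816 and, with an estimated correlation, an adjusted p = 0.112, with APLNR up 31.5-fold and CXCR4 up 6.43-fold. Arterial genes (2 of 14 up, 4 adjusted over the list alone) had an adjusted p = 0.0394 and an adjusted p = 0.296 with an estimated correlation. Their call also ended without layers replicate 2 (adjusted p = 0.122) or monoculture replicate 4 (adjusted p = 0.129). Notch signalling genes (3 of 21 up, 4 adjusted over the list alone) had an adjusted p = 0.0530, and an adjusted p = 0.0241 with the donor as a block, which was lost with an estimated correlation under the block (adjusted p = 0.204). Venous and lymphatic genes (3 of 10 up, 3 up and 1 down adjusted over the list alone) had an adjusted p = 0.0539, with LYVE1 up 9.34-fold.

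Both cell cycle lists passed in layers, with an adjusted p = 2.50e-32 for mitosis and 3.66e-20 for DNA replication, and an adjusted p = 0.112 for each with an estimated correlation. Adjusted over the list alone 30 of 30 and 26 of 27 genes fell. Cholesterol synthesis genes also fell as a list, with 6 of 16 down (7 adjusted over the list alone), by a median of 1.28-fold, and DHCR7, which makes cholesterol in the last step of a synthesis branch, down 1.54-fold (adjusted p = 3.57e-05, adjusted p = 0.141 with an estimated correlation). Flow-responsive (3 of 14 up), immediate early (8 of 19 up), hypoxia and glycolysis (8 of 25 up), unfolded protein (5 of 19 up), and vascular growth factor genes (7 of 28 up, 1 down) passed with adjusted p of 0.00444, 1.66e-06, 5.92e-09, 0.000816 and 0.00496. With an estimated correlation these lists had adjusted p of 0.112, 0.112, 0.139, 0.199 and 0.141. Adjusted over the list alone 4, 14, 12, 7 and 9 of their genes rose and 0, 1, 0, 1 and 1 fell. NF-kB genes (5 of 21 up, 1 down, 7 and 2 adjusted over the list alone) had an adjusted p = 0.00478 and, with an estimated correlation, an adjusted p = 0.266. Their call ended with array weights (adjusted p = 0.0553) and without layers replicate 1 (adjusted p = 0.0780).

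In layers, TGF-beta and BMP response genes (4 of 25 up, 1 down, adjusted p = 0.231) had a median of -0.02 and a mean of 0.26, with TGFBI up 28.5-fold (45.1-fold without layers replicate 1) and ID2 up 5.35-fold, and the list did not pass. Nor did interferon response (2 of 23 up, adjusted p = 0.270), YAP and SRF targets (1 of 16 up, 1 down, adjusted p = 0.231), axon guidance (4 of 27 up, 1 down, adjusted p = 0.163) and leukocyte and erythroid markers (0 of 5, adjusted p = 0.231). Cell junction genes (1 of 18 up, 1 down, adjusted p = 0.447) had a median of 0.00 and a mean of -0.27, with the tight junction gene OCLN down 3.24-fold. Adjusted over the list alone, 4, 2, 1, 8, 0 and 1 genes of these 6 lists rose and 2, 0, 1, 3, 0 and 1 fell.

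**Figure D2:**
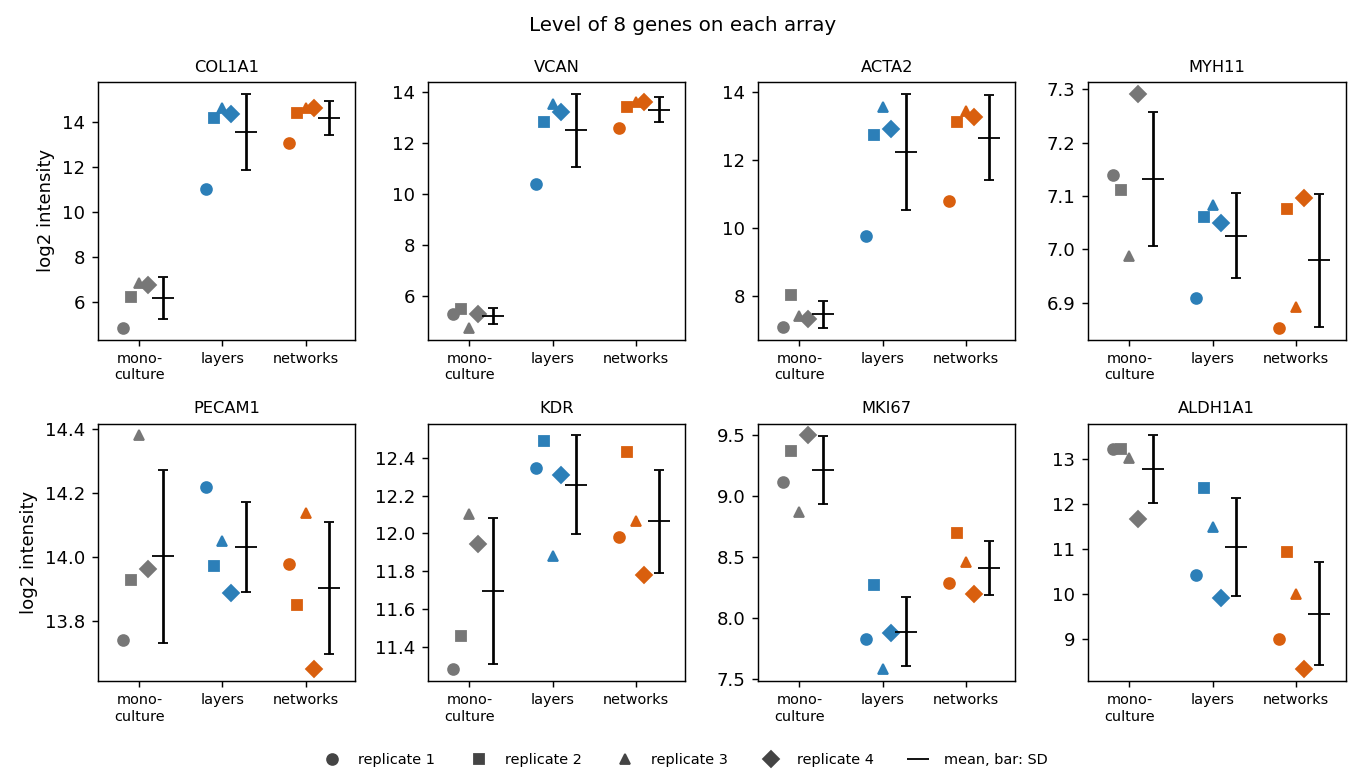
Log2 intensity of 8 genes on each of the 12 arrays, with 1 panel per gene, points shaped by donor, and the group mean with a bar of 1 SD (n = 4). COL1A1, VCAN and ACTA2 were higher and MKI67 and ALDH1A1 lower in networks than in monoculture, while MYH11, PECAM1 and KDR did not pass. MYH11 was dim, with group means from 6.98 to 7.13 against a table median of 6.48.

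Changes in networks and in layers against monoculture ran largely in parallel. Of the genes tested, 746 rose in both and 773 fell in both, and 0 were called in opposite directions. Independent lists of these lengths would share 93.0, 100 and 193 genes, and simulated unchanged groups against the same controls gave 0 in each class. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.956 and rho = 0.894, against a simulated mean r of 0.501 and a highest of 0.543 from the shared controls alone. The covariance was 0.341, of which the shared controls gave 0.0196 in simulation, a difference of 0.321. In a simulation that also paired the noise of networks and layers by donor, added after the result was seen, the mean r was 0.888, the highest 0.903 and the covariance 0.0350, a difference of 0.306. It gave at most 1 gene up and 1 gene down in both. With the monoculture arrays split between the comparisons, r lay between 0.856 and 0.925 over 6 splits, with 252 to 329 genes up and 236 to 322 down in both.

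**Figure D3:**
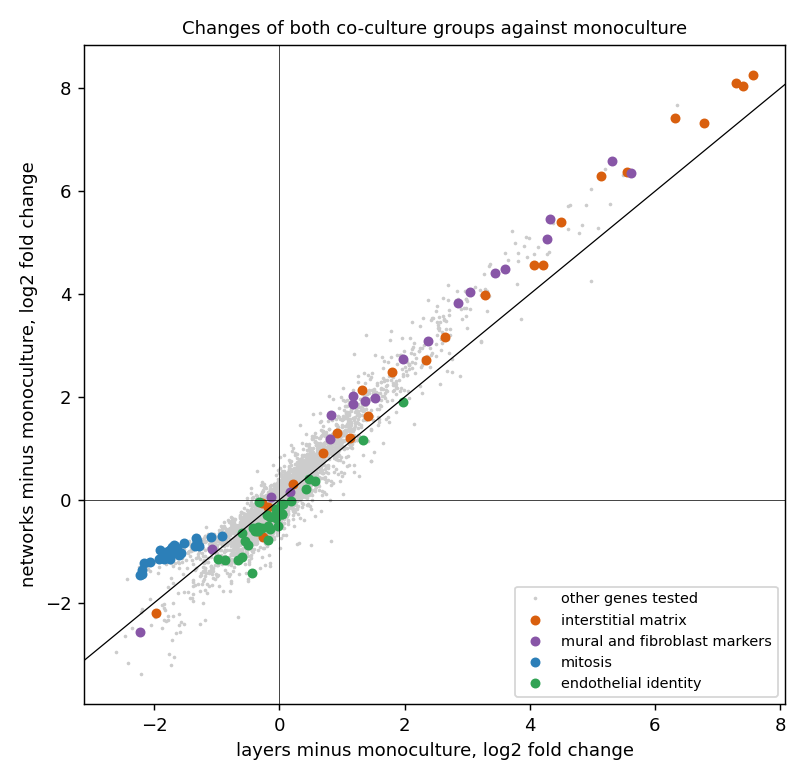
Log2 fold change of each of the 13346 genes in networks against monoculture (vertical axis) and in layers against monoculture (horizontal axis), with the line of equal change and the members of 4 gene lists in colour. The 30 mitosis genes lay below 0 on both axes, with medians of -0.99 in networks and -1.73 in layers.

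With the donors unpaired, 1 gene passed in limma between networks and layers, GIMAP2, a GTPase of the immunity-associated family, which was 1.63-fold lower in networks (10.002 ± 0.10 against 10.71 ± 0.11, SD, n = 4, adjusted p = 0.0430, lower in 4 of 4 donors). At an unadjusted p under 0.05 there were 882 genes, and the groups did not overlap for 3.12% of genes, against 2.86% by chance. As a group, the 30 mitosis genes were all higher in networks, by a median of 1.66-fold. None of them passed over all genes, and 29 rose adjusted over the list alone. With the donor as a block, 0 genes passed in this comparison. GIMAP2 then had an adjusted p = 0.0579, and its call ended without any of the 12 arrays (adjusted p from 0.0534 to 0.271). It passed with the donor as a block over the 8 co-culture arrays (adjusted p = 0.0239), the paired fit below.

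By the list test, 11 of 26 lists differed between networks and layers, 8 higher and 3 lower, and 0 did with an estimated correlation. Mitosis (adjusted p = 4.23e-31, adjusted p = 0.136 with an estimated correlation), DNA replication (26 of 27 genes higher, adjusted p = 3.23e-08 and 0.376 with an estimated correlation) and cholesterol synthesis (16 of 16 higher, adjusted p = 3.62e-06 and 0.157 with an estimated correlation) were higher in networks. So were mural and fibroblast markers (18 of 20 higher, adjusted p = 0.000247 and 0.378 with an estimated correlation), interstitial matrix (22 of 25, adjusted p = 0.00904 and 0.570 with an estimated correlation), and matrix proteases (17 of 25, adjusted p = 0.00117 and 0.136 with an estimated correlation). The flow-responsive (10 of 14, adjusted p = 0.00906 and 0.136 with an estimated correlation) and NF-kB lists (17 of 21, adjusted p = 0.00746 and 0.378 with an estimated correlation) were the remaining ones higher in networks. Endothelial identity genes were lower in networks (34 of 35, adjusted p = 1.45e-08 and 0.279 with an estimated correlation), as were venous and lymphatic (9 of 10, adjusted p = 0.00904 and 0.136 with an estimated correlation) and tip cell genes (13 of 19, adjusted p = 0.0352 and 0.279 with an estimated correlation). Several of these calls ended under other settings. The tip cell call ended without the filter (adjusted p = 0.0733), with the mean of probe sets (0.0759), with centring (0.0682), with repeated quantile normalization (0.0505), and without networks replicate 1 (0.219), layers replicate 2 (0.0854) or layers replicate 4 (0.115). The venous and lymphatic call ended with the stricter filter (adjusted p = 0.103) and without layers replicate 4 (0.0621), and the flow-responsive call without layers replicate 1 (0.129). The NF-kB call ended without networks replicate 1 (adjusted p = 0.137), which stood apart in this list, or layers replicate 4 (0.104), and the matrix call with array weights (0.0520) and without networks replicate 3 (0.0533) or 4 (0.107). Integrins did not pass (adjusted p = 0.0597), passed with the donor as a block (adjusted p = 0.0457), and did not pass with an estimated correlation under the block (adjusted p = 0.260). Apart from mitosis, 1 flow-responsive gene rose and 1 endothelial identity and 1 interferon gene fell adjusted over the list alone. Contractile (adjusted p = 0.126), basement membrane (0.530, median -0.09, mean 0.06), Notch (0.597), arterial (0.597), TGF-beta and BMP (0.190), interferon (0.325), hypoxia (0.194), YAP and SRF (0.730), cell junction (0.126), immediate early (0.373), unfolded protein (0.597), growth factor (0.194), axon guidance (0.194) and leukocyte genes (0.0560) did not pass. Without layers replicate 1, which had the lowest mural and fibroblast mean, the matrix list median was -0.09 (adjusted p = 0.436) and the mural list did not pass (adjusted p = 0.278). COL1A1 (0.64 ± 0.75 SE), ACTA2 (0.41 ± 0.78), TAGLN (0.36 ± 0.54), CNN1 (0.08 ± 0.38), MYH11 (-0.05 ± 0.08), PECAM1 (-0.13 ± 0.14), CDH5 (-0.18 ± 0.17), KDR (-0.19 ± 0.20), VWF (-0.59 ± 0.18) and MKI67 (0.52 ± 0.17) did not pass between networks and layers (adjusted p from 0.516 to 0.989). In the paired fit of the next paragraph, with the donor as a block over 8 arrays, MKI67 (adjusted p = 0.0457) and VWF (adjusted p = 0.0320) passed.

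A paired fit over the 8 co-culture arrays alone, with the donor as a block, was chosen after these results were seen and is 1 of 27 other settings run for this comparison. It called 463 genes, 257 higher and 206 lower in networks, of which 48 changed at least 2-fold, and 2871 had an unadjusted p under 0.05. The count fell to 1 without replicate 2 and to 1 without replicate 4, and was 179 without replicate 1. By the fixed rule, its largest rises were TSPAN8 (3.52-fold), RAB27B (3.10-fold), CYP1B1 (2.84-fold), AADAC (2.84-fold) and HGF, hepatocyte growth factor (2.83-fold), with OSR1, ADAMTS5, AKR1C1, the chemokine CXCL12 and STATH from 2.54-fold to 2.38-fold. Its largest falls were CXCL11, an interferon-induced chemokine (3.09-fold), CYP1A1 (3.04-fold), ALDH1A1 (2.80-fold), BMP4 (2.598-fold) and LRATD2 (2.34-fold), then ADAMTS18, ARHGAP28, SLC40A1, EDN1 and SELP from 2.27-fold to 2.21-fold. The call of ALDH1A1 (adjusted p = 0.000743) held without any 1 donor, and those of the other 19 genes ended without replicate 2 and without replicate 4. Of the 257 rises, 162 were also called as rises in networks against monoculture, and of the 206 falls, 124 as falls there. Both comparisons use the same networks arrays, so part of this is shared by design. A different share of mesenchymal RNA in networks and layers cannot be told apart here. The extract gives no share per cell type.

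In the paired fit 9 of 30 mitosis genes rose (30 adjusted over the list alone), including HMMR (1.93-fold) and NDC80 (1.74-fold), and 4 of 20 mural and fibroblast markers rose (14 up and 1 down adjusted over the list alone). Of 35 endothelial identity genes 4 fell (10 adjusted over the list alone), including MMRN1 (2.00-fold) and VWF (1.51-fold), and of 19 tip cell genes 4 fell and 1 rose (6 and 2 adjusted over the list alone), including NRP2 (1.53-fold) and ANGPT2 (1.43-fold). The paired fit called 14 lists, and 0 with an estimated correlation (smallest adjusted p = 0.358). Besides the 11 lists called without pairing these were integrins (adjusted p = 0.0153), contractile (adjusted p = 0.0249) and TGF-beta and BMP response genes (adjusted p = 0.0481).

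**Figure D4:**
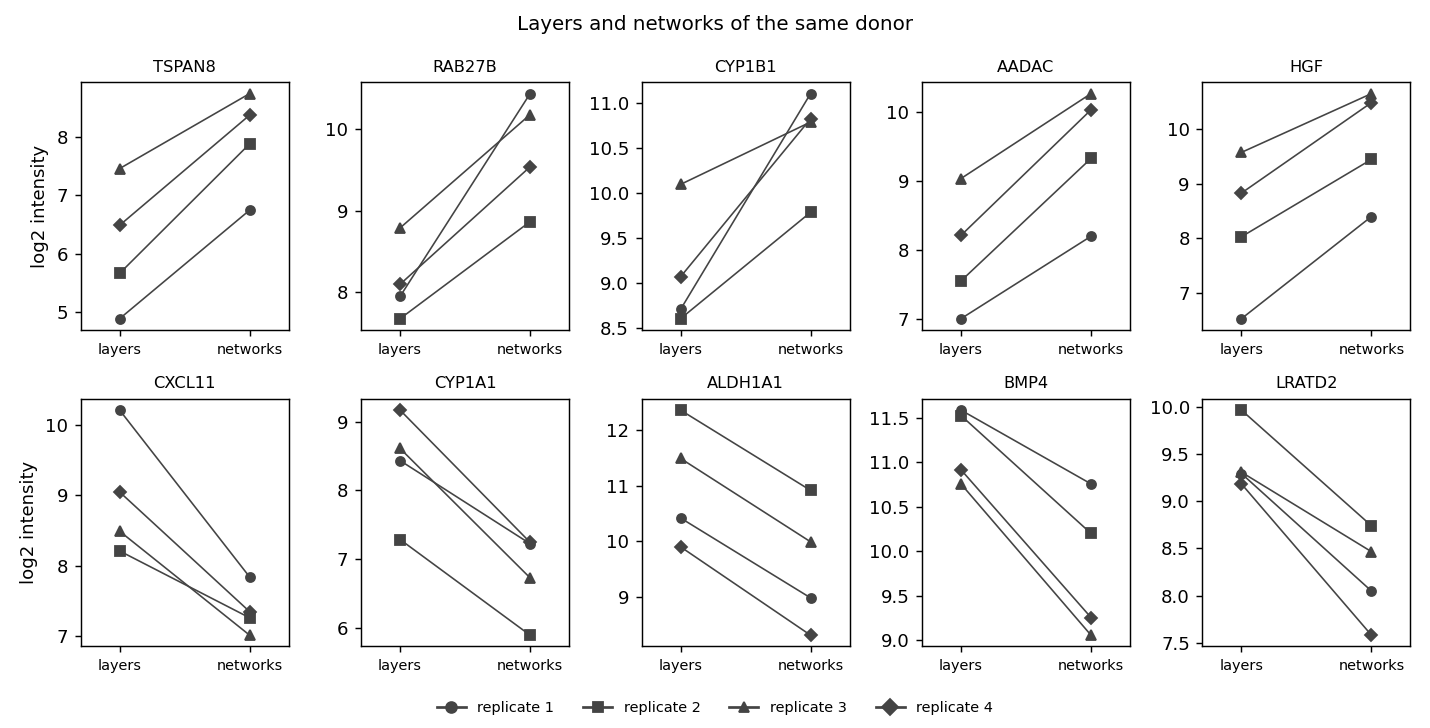
Log2 intensity of the 5 largest rises and 5 largest falls of the paired fit in layers and networks, with 1 line and symbol per donor. All 4 lines run the same way in each of the 10 panels, as the rule for choosing these genes required.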

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

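The RNA quality and NF-kB tests below were chosen only after the result was seen, and their bounds were set after their values. In groups of 4 arrays, a value was picked out when its gap to the nearest other array as a share of the group's range was above Dixon's 95% critical value. This picked out 9 of 93 array measures and 39 of 399 sets of gene values, where chance gives about 4.65 and 19.95. Of the 48 values, 24 were in networks replicate 1 and 8 in layers replicate 1.

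In networks replicate 1, matrix and mural genes were low. COL6A3 stood at 12.16 (others 14.17 to 14.34), COL1A1 at 13.08 (14.42 to 14.65), COL3A1 at 13.71 (14.59 to 14.75), COL6A1 at 11.44 (13.51 to 13.89), TGFBI at 12.99 (14.07 to 14.24), FBLN1 at 7.199 (10.6 to 11.25), NID2 at 10.61 (12.21 to 12.43) and IL13RA2 at 8.399 (11.94 to 12.65). ACTA2 stood at 10.79 (13.12 to 13.45), TAGLN at 12.19 (13.24 to 13.43) and the contractile list at 9.867 (10.32 to 10.39). Also low were STATH at 6.844 (9.225 to 9.551), SEMA6A at 6.261 (7.355 to 7.538), UNC5B at 8.818 (10.43 to 10.57), VCAM1 at 5.665 (6.609 to 6.728), FOS at 8.894 (10.22 to 10.41), ZFP36 at 9.623 (10.58 to 10.74), ACAT2 at 8.641 (9.438 to 9.535) and the interferon list at 7.922 (8.069 to 8.083). High were CXCL6 at 13.4 (9.973 to 10.3), CXCL1 at 13.56 (10.62 to 11.1), NTN4 at 11.2 (10.26 to 10.4), TAL1 at 10.17 (9.235 to 9.274) and the second principal component at 40.14 (-7.252 to -4.241).

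In layers replicate 1, COL6A3 stood at 9.845 (others 13.91 to 14.29), COL1A1 at 11.04 (14.19 to 14.63), COL3A1 at 11.74 (14.48 to 14.8), TGFBI at 11.36 (13.83 to 14.33), NID2 at 10.18 (11.73 to 11.96), ZFP36 at 9.329 (10.41 to 10.55) and the basement membrane list at 11.53 (12.18 to 12.25). Its second principal component was 32.79 (-9.846 to -5.061).

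In layers replicate 2, LYVE1 was low at 10.38 (11.24 to 11.41), while HERC5 at 7.695 (6.623 to 6.805), LRATD2 at 9.963 (9.182 to 9.306) and the cell junction list at 11.27 (11.07 to 11.1) were high. In layers replicate 3, the 3' to 5' difference was 0.1777 for GAPDH (0.2635 to 0.2787) and 0.8905 for ACTB (0.5502 to 0.5736), and EPHB4 stood at 10.7 (11.19 to 11.22). In networks replicate 4, GPC5 stood at 5.03 (6.167 to 6.332). In monoculture, the protease list stood at 8.668 in replicate 1 (9.138 to 9.205) and TSPAN8 at 5.743 in replicate 2 (4.26 to 4.502). In monoculture replicate 3, COL15A1 stood at 7.741 (3.751 to 4.18), THBS1 at 14.1 (13.92 to 13.95) and UNC5B at 8.53 (8.27 to 8.309). In monoculture replicate 4, ALDH1A1 stood at 11.66 (13 to 13.21), COL8A1 at 12.69 (13.28 to 13.33) and GUCY1A1 at 7.574 (8.891 to 9.105).

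Replicate 1 of both co-culture groups stood apart. Of the 4 GAPDH and ACTB 3' to 5' differences of these 2 arrays, 3 lay above all others of their group and 0 outside the range of the other 10 arrays, which leaves RNA quality open. A smaller share of mesenchymal RNA could lower the matrix and mural genes. The NF-kB list lay above the endothelial identity list by 0.25 in the array with the smaller difference (bootstrap 95% interval over genes, -0.01 to 1.54). That interval alone leaves open whether the NF-kB list needs another cause. The list mean was 9.76 in networks replicate 1 and 9.48 in layers replicate 1. The other co-culture arrays lay from 8.31 to 8.94 and monoculture from 7.90 to 8.33. If endothelial cells kept their monoculture level, a smaller mesenchymal share would bring the list nearer to monoculture. These values argue against that share as the cause of the higher NF-kB list in these 2 arrays. No biological explanation was tested, and a difference between the cultures of this replicate stays open.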

How the results depend on the processing

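The fits without replicate 1 or its co-culture arrays, and those with the donor as a block over 8 arrays, were chosen only after the result was seen. Against 3088 genes in networks against monoculture, there were 5270 with every probe set on its own, 4924 with array weights and 777 at a fold change of at least 2. Against 1670 in layers against monoculture, there were 2698 with the donor as a block, 1148 as a block over 8 arrays, 2813 as a random block, 2787 with every probe set, 3703 with array weights, 516 at a fold change of at least 2, 2645 without replicate 1 and 3267 without its co-culture arrays. Against 1 in networks against layers, there were 0 with the donor as a block, 6 as a random block, 2 with the mean of probe sets, 2 with every probe set, 2 with centring, 2 with repeated quantile normalization, 0 over 8 arrays, 13 with array weights, 0 at a fold change of at least 2, 2 without the co-culture arrays of replicate 1 and 463 in the paired fit over 8 arrays. That paired fit gave 48 at a fold change of at least 2 and 1 to 636 without 1 donor. With an estimated correlation 1, 1 and 0 lists passed, against 15, 17 and 11, and 0 against 14 in the paired fit.

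Leaving out each array gave 2084 to 3606 genes in networks against monoculture, 1003 to 2232 in layers against monoculture (1003 without layers replicate 3, 1035 without layers replicate 4) and 0 to 1 in networks against layers (1, another gene, only without networks replicate 1). Including the fits without replicate 1 the highest counts were 4394, 3267 and 2. Lists numbered 15 to 17, 16 to 19 and 8 to 13. The correlation of the 2 comparisons against monoculture was 0.86 to 0.92 (0.856 to 0.925) with split controls and 0.931 (without layers replicate 3) to 0.960 with arrays left out, against 0.956.

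Some small differences turned. PECAM1 was 0.027 in networks against monoculture without monoculture replicate 3 (lowest -0.21), and in layers against monoculture -0.031 with the mean of probe sets, -0.013 with array weights, -0.033 without layers replicate 1, -0.06 without monoculture replicate 1 and -0.12 without replicate 1 (highest 0.16). In networks against layers without layers replicate 1, COL1A1 was -0.20 (highest 1.01), ACTA2 -0.42 (1.04), TAGLN -0.16 (0.69), CNN1 -0.16 (0.49) and the matrix list -0.092 (0.78). CNN1 was -0.00, -0.04 and -0.12 without networks replicates 2, 3 and 4. None of these genes passed in these comparisons.

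Over all settings, named genes kept their call and direction in 2267, 1865 and 269 cases for the 3 comparisons, lost a call in 94, 86 and 17, gained one in 7, 6 and 2 and turned in 1, 6 and 7. Lists kept theirs in 359, 400 and 243 cases, lost a call in 16, 25 and 31 and turned in 0, 0 and 1. In networks against monoculture, 4146 genes changed with the donor as a block over all 12 arrays, against 3088. The counts were 4320 as a random block and 2473 as a block over 8 arrays. The donor as a block over all 12 arrays changed no call of a named gene or a list apart from those given in the report. As a block over 8 arrays it ended the calls of CDH5, THBS1 and ACAT2 in networks against monoculture and of FBLN2, NOTCH3, ITGA11, ASNS, VEGFA, P4HA2, PDGFD, LYL1, ACAT2 and the integrins in layers against monoculture. List tests with the donor as a random block were not run. The cause was not tested for any of these. Signal near background limits the fold changes of dim genes.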

Other observations

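The tests of mesenchymal RNA, of mitosis genes and of endothelial genes below, and the paired fit, were chosen only after the result was seen. Cholesterol synthesis genes were lowest in layers. The list fell in layers against monoculture, by a median of 1.28-fold (adjusted p = 0.141 with an estimated correlation), and did not pass in networks against monoculture (median -0.06). Between the co-cultures all 16 of its genes were higher in networks, though 0 of them passed over all genes and the list had an adjusted p = 0.157 with an estimated correlation. In the paired fit, with the donor as a block, 5 of 16 rose (10 adjusted over the list alone), including squalene epoxidase SQLE (1.38-fold, adjusted p = 0.0320) and the methylsterol oxidase MSMO1 (1.38-fold, adjusted p = 0.0363).

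Axon guidance and interferon genes went both ways in the paired fit. SLIT3 and UNC5B rose 1.44-fold and 1.32-fold while SEMA6A and SEMA3G fell 1.74-fold and 1.73-fold, and the axon guidance list did not pass (adjusted p = 0.172). IFI44L and IFIT3 rose 1.54-fold and 1.51-fold while HERC5 fell 1.42-fold and the chemokine CXCL11 3.09-fold, and the interferon list did not pass (adjusted p = 0.112). The Notch ligand DLL1 fell 1.71-fold. Of the 12 arrays, 1 was closer on average to the other kind of culture. On the first principal component, layers replicate 1 was the co-culture array nearest to monoculture. It stood at -16.6, against 15.2 to 39.2 in the other layers arrays and -46.1 to -42.9 in monoculture.

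Many genes dim in monoculture were far higher in both co-culture groups. The 92 such genes that rose at least 4-fold in both were chosen by their rise, and 13 of them were in the mural, matrix or contractile lists. They lay on the same side of their group mean in 84.1% of cases per array on average, against a median of 57.5% and a highest value of 64.8% over 1000 random lists. RNA of the co-cultured mesenchymal cells in the extract could give this. So could any genes regulated together, because the random lists were matched by expression level alone. The endothelial identity list had a median change in networks of -0.34 (bootstrap 95% interval over genes, -0.56 to -0.27). That list cannot exclude endothelial cells that took on mesenchymal genes, since dilution lowers it too. The culture itself, a biological difference, stays open and untested.

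Mitosis genes fell in both co-culture groups, more in layers. Their median change lay below that of the endothelial identity list by -0.65 in networks (interval over genes, -0.74 to -0.41). In layers it was -1.58 (-1.70 to -1.39). The intervals leave out the spread between donors, and mitosis genes varied together (estimated correlation 0.72). By array, the mitosis list averaged 9.39 to 10.09 in monoculture and 7.62 to 8.48 in layers. The identity list averaged 11.61 to 11.86 and 11.33 to 11.80. This argues against dilution of endothelial RNA as the whole cause in layers. In networks replicate 3 the identity list fell as far (11.86 to 11.32) as mitosis (9.39 to 8.91), unlike in the other replicates. Dilution therefore stays open in networks. Between networks and layers the median change of mitosis genes lay above that of the identity list by 0.97 (0.88 to 1.03). In each replicate the mitosis list was higher and the identity list lower in networks than in layers. This argues against less dilution in networks. Dividing smooth muscle cells in networks cannot be told apart from dividing endothelial cells by the median of 0.74, because the extract gives no share per cell type. Network formation against a confluent layer, a biological difference, stays open and untested.

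All 35 splits of the 8 arrays of each comparison were fitted, the real split among them. The counts of splits that gave as many include the real split. For genes, only the real split gave as many in networks against monoculture (3088, highest other 0). In layers against monoculture it was also the only 1 (1670, highest other 0). Every other split mixes co-culture and monoculture arrays, which widens the spread within groups and makes low counts likely in advance. Of the 35, only 8 part all donor pairs, too few for a share under 0.05, so chance could not be excluded. Among those 8 too the highest other was 0. In networks against layers 4 splits gave as many as the real 1, the highest 394, so chance could not be excluded. That split kept same-donor arrays together, which points to a structure shared by the 2 co-cultures of a donor. Across genes, deviations of same-donor arrays correlated at a mean of 0.77 between networks and layers. The mean was 0.07 between networks and monoculture and 0.10 between layers and monoculture, so the donor alone is not shown as the cause. Among the 8 splits that part all donor pairs, only the real split called any gene (highest other 0). For lists, 4 splits gave as many in networks against monoculture (15, highest other 19), 3 in layers against monoculture (17, highest other 20) and 4 in networks against layers (11, highest other 13), so chance could not be excluded. In the paired fit, the 8 splits that part the pairs are too few for a share under 0.05, with 1 split giving as many as 463 genes (highest other 0) and 2 as many as 14 lists (highest other 14).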
